A study of Drosophila melanogaster with 22 samples.

How the data were processed

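Messenger RNA levels were measured in cultured Drosophila S2 cells on 22 one-colour Affymetrix arrays. Cells had been treated with double-stranded RNA (dsRNA) against GFP, a sequence S2 cells lack, or against 1 of 9 subunits or partners of the RNA exosome, the complex that degrades and trims RNA from its 3' end. The labels give dsRNA at 30 µg/ml on days 0, 1 and 3, harvest on day 5, and 6 µg of total RNA per array. Each group had 2 arrays, except Rrp4 with 4. The titles call the depletion arrays biological replicates and number the GFP arrays as controls. The sources used here do not say whether replicates were separate cultures, so the spread between arrays of a group is that of whatever was replicated.

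The authors deposited probe set intensities on a linear scale, made with the Affymetrix software GCOS, whose version the labels do not give. In the deposited intensities, the mean after trimming 2% at each end was 500 on all 4 Rrp4 arrays and ranged from 125.9 to 345.6 on the other 18. Because trimmed means differed by more than 5%, all arrays were quantile normalized here, which gives every array the same distribution of values. Values were floored at the 10th percentile of all values (a signal of 3.234) and taken as log2. Of 18952 probe sets, 183 Affymetrix controls were left out. The 9385 probe sets at or above the median of mean log2 signal (4.67) were tested, and 0.0475% of their values lay at the floor. A gene at the floor on every array of a group has no measured size, only a lower bound, and one at the floor on some arrays has a size that depends on the floor. For arrays, precision is limited by their number. Correlations of log2 signal between arrays of a group were 0.931 to 0.965.

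One linear model with 10 group means was fitted to the 22 arrays with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, leaving 12 residual degrees of freedom. All groups thus share 1 estimate of spread per probe set, and fold changes are given as log2 with the standard error (SE) from this fit. The groups were not equally variable. The median absolute log2 difference between 2 arrays of a group was 0.435 in Rrp6, 0.413 in Dis3, 0.343 in Csl4 and 0.305 in GFP. In the other groups it was 0.123 (Rrp46) to 0.230 (Mtr3). The shared SE can therefore be too small for the more variable groups, among them the GFP control. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. All tests of this model were two-sided. Comparisons were each depletion with GFP, the mean of the 9 depletions with GFP, the F test over the 9 depletions, each depletion with the other 8, and 4 comparisons of subunit classes. The core class held Csl4, Mtr3, Rrp4, Rrp40, Rrp46 and Ski6, which form the ring and cap of the complex. It was compared with Rrp6 and Rrp47, with Dis3, and these with each other.

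The samples, comparisons, gene lists, rule for named genes and most other settings were fixed before the data were examined. Of the 9385 probe sets, 7825 carried 1 gene symbol in the tables used, and these stood for 7222 genes. Named genes had 1 symbol and an adjusted p under 0.05, with every depletion array on the same side of both GFP arrays where GFP was compared, and were ranked by absolute log2 fold change. The rule took the 12 highest and 12 lowest genes for all depletions against GFP, 5 and 5 for each depletion and each class comparison, and 3 and 3 for each depletion against the other 8. It also took the 9 targeted genes, the other measured exosome genes, the 2 highest and 2 lowest members of a described list, and list members called in all 9 depletions.

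The 23 lists covered exosome subunits and cofactors, other mRNA decay factors, replication-dependent histones, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, proteasome, heat shock and chaperones, antimicrobial peptides and immune signalling, JAK-STAT targets, mitosis, DNA replication, noncoding RNAs and snoRNA hosts, hemocyte lineage, neuronal markers, muscle markers, germline markers, apoptosis and DNA damage, endoplasmic reticulum stress, aminoacyl-tRNA synthetases, oxidative phosphorylation, small RNA pathway and ecdysone response. Each gene was represented by its brightest probe set. Lists were tested against the other genes with limma's camera at a preset correlation between genes of 0.01, then with an estimated correlation, and with fry, which asks whether a list moves on balance one way without comparing it with other genes. The 280 list tests (20 lists in 14 comparisons) were adjusted as 1 family.

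Tested on simulated data with the real means and spreads, the pipeline called 44 of 48 probe sets lowered 4-fold in Csl4, 40 of 50 raised 4-fold, 33 of 48 lowered 2-fold and 31 of 50 raised 2-fold. It called 13 of 9189 unchanged probe sets. With the 4 Rrp4 arrays it called 41 of 45 and 45 of 50 at 4-fold, 32 of 48 and 35 of 50 at 2-fold, and 10 of 9192 unchanged ones. Changes of 2-fold were therefore missed often, and smaller ones, which were not simulated, can be missed too. The simulated noise was independent between arrays, with the same spread in every group and no offset of the GFP arrays. The real groups differed in spread and some arrays deviated together, so the low rate of false calls need not hold for them.

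Other settings tried were the values as deposited, median centring, other floors, filters and thresholds, a fit without trend, array weights, a term for replicate number, a fit of only the groups compared, the subunit as a random block, and leaving out each array in turn. Where a group then has 1 array, that array is assumed to vary like the other groups. Replicate numbers did not pair the samples across groups in general, although arrays of the same number in Csl4, Dis3 and Rrp6 deviated together, as given below. Among 90 pairs of arrays with the same number in different groups, 8 had residuals correlated above 0.1, and the range was -0.348 to 0.411. Leaving out the Rrp4 arrays, pairs of them, the 9 target probe sets, or Csl4 2, Dis3 2 and Rrp6 2 together was chosen after seeing the data, as were the tests of the core class against Rrp6 alone and Rrp47 alone.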

Results

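Expression was measured in Drosophila S2 cells, a line derived from embryonic blood cell-like cells, after dsRNA treatment. There were 2 arrays of cells given GFP dsRNA and 20 arrays of cells labelled as depleted of an exosome component: 4 for Rrp4 and 2 each for Csl4, Rrp40, Mtr3, Rrp46, Ski6, Dis3, Rrp6 and Rrp47. Csl4, Rrp4 and Rrp40 are cap subunits and Mtr3, Rrp46 and Ski6 ring subunits, while Dis3 and Rrp6 are exonucleases and Rrp47 is the partner of Rrp6. The series was made to find the mRNAs that exosome subunits act on. Several targeted genes were not lower in their own arrays, so groups are named by their labels throughout. The 4 Rrp4 arrays also stood apart in the controls: poly-A spike-in signal relative to hybridization controls was -4.55 to -2.16 (log2) on them and 1.10 to 2.71 on the other 18. They also split among themselves, at -4.32 and -4.55 on Rrp4 1 and 2 and at -2.16 and -2.40 on Rrp4 3 and 4. The signal of the Rrp4 gene split the same way, as given below. The control probe sets for 18S ribosomal RNA had a mean log2 signal of 8.93 ± 1.37 (SD, n = 2) on GFP arrays, 13.63 ± 0.05 (n = 2) on Dis3 arrays and 7.62 ± 0.79 (n = 4) on Rrp4 arrays.

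**Figure D1:**
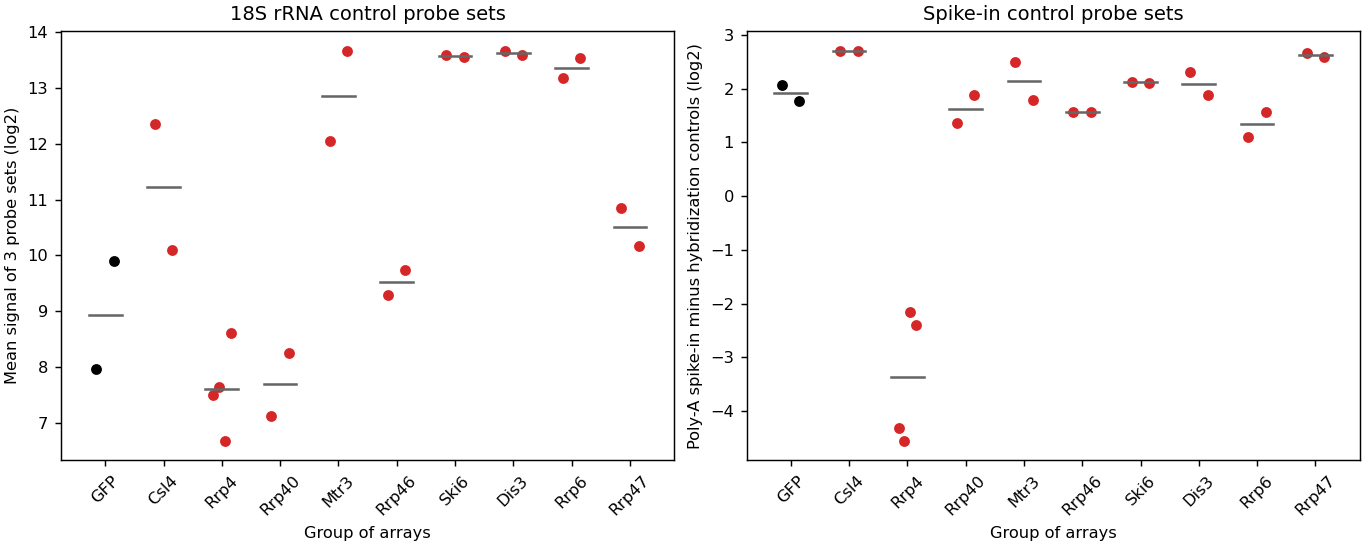
Control signals of each of the 22 arrays by group, with 1 point per array: 18S ribosomal RNA signal (log2) and poly-A spike-in minus hybridization control signal (log2). In spike-in signal the 4 Rrp4 arrays lie at -4.55 to -2.16, below the 1.10 to 2.71 of the others.

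The first comparison asked whether each targeted gene was lower in its own arrays. Csl4 rose in the arrays labelled Csl4, by 2.68 ± 0.26 (log2 fold change against GFP ± SE; 6.40-fold, adjusted p = 1.3e-06). Ski6 rose by 2.40 ± 0.32 in its own arrays (adjusted p = 3.1e-05), Rrp40 by 1.83 ± 0.24 (3.5e-05) and Rrp47 by 1.71 ± 0.23 (4.8e-05). For these 4 genes, both own arrays lay above all other arrays. Their probe sets may also detect the dsRNA itself, as weighed below, so a higher signal need not be more mRNA. Dis3, the catalytic subunit, fell by 1.17 on the log2 scale (SE 0.32, adjusted p = 0.014) and Rrp6 fell by 0.91 (SE 0.27, adjusted p = 0.046), with both own arrays below both GFP arrays. Rrp46 did not pass the test at 0.50 ± 0.24 (adjusted p = 0.15), nor did Mtr3 at 0.48 ± 0.49 (adjusted p = 0.56) or Rrp4 at -0.60 ± 0.68 (adjusted p = 0.55). Own arrays often disagreed on their target. Its SD was at percentile 100 of probe sets of similar signal for Rrp4 and Mtr3. The percentile was 99.9 for Rrp46, 99.8 for Rrp47 and 99.4 for Ski6. It was 87.6 for Csl4, 86.1 for Rrp6, 82.3 for Rrp40 and 71.7 for Dis3.

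The Mtr3 arrays read 6.91 and 9.39 for their target, and without array 1 the change was 1.72 and called, while without array 2 it was -0.77 and not called. The Rrp4 arrays read between 7.11 and 10.79, their change was 0.80 and not called with arrays 1 and 2 alone, and -1.999 and called with arrays 3 and 4 alone. With the values as deposited it was 1.04 and not called for Rrp4, and 1.61 and called for Mtr3. The call for Dis3 was lost without GFP 2 (-1.10, adjusted p = 0.075) or Dis3 2 (-0.81, adjusted p = 0.15), and that for Rrp6 without GFP 1 (-1.12, adjusted p = 0.062), GFP 2 (-0.70, adjusted p = 0.24) or Rrp6 1 (-0.45, adjusted p = 0.28). Without Rrp46 1, Rrp46 reached 0.86 and was called (adjusted p = 0.043). Adjusted over the 9 targets alone, the same 6 genes passed.

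**Figure D2:**
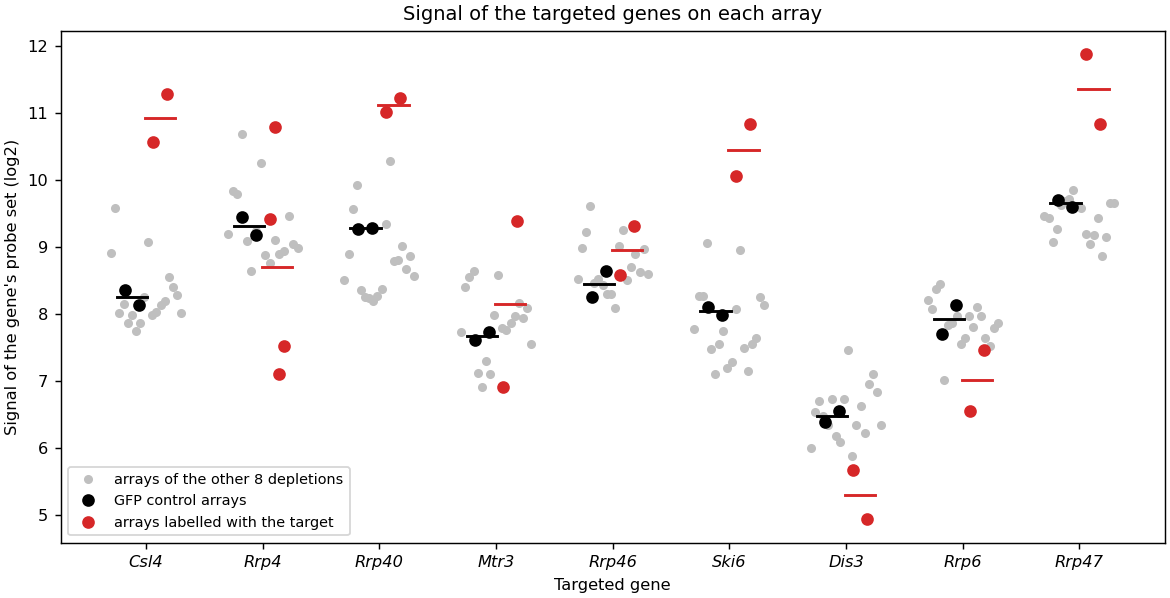
Log2 signal of each targeted gene's probe set on every array, with the gene on the horizontal axis and 1 point per array, by whether the array is labelled with that gene's depletion, with GFP or with another depletion. Own arrays lie above all others for Csl4, Rrp40, Ski6 and Rrp47, and below both GFP arrays for Dis3 and Rrp6.

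Taking all 9 depletions against GFP, the gene furthest above GFP was CG4250, higher by 6.17 ± 0.20 (72.1-fold) and among the 5 highest named genes in each of the 9 depletions. CG15695 (5.09 ± 0.36), CG18557 (4.98 ± 0.20), Erasp (4.54 ± 0.40), CG5381 (4.34 ± 0.26) and CG12470 (4.21 ± 0.25) followed. Sarm, a TIR-domain NAD hydrolase of axon degeneration, rose by 4.06 ± 0.29, SerT, the serotonin transporter, by 3.85 ± 0.11, and sn, the actin-bundling fascin, by 3.38 ± 0.36. CG12947 (3.69 ± 0.52, at the floor in 1 of 2 GFP arrays), Phk-3 (3.60 ± 0.22) and CG14419 (3.39 ± 0.22) complete the 12 highest. Apart from CG18557 (5.66), SerT (5.51) and Phk-3 (4.97), these had mean log2 GFP signals of 1.81 (CG12947) to 4.12 (CG14419), with 2.77 for CG4250. Those lie below the 4.67 used to choose probe sets, so the sizes, here and in single depletions, rest on weak GFP signals. On the lower side, the cuticle protein gene Cpr64Ac changed by -4.11 ± 0.59, ringer, a microtubule-binding protein, by -3.41 ± 0.22, and gsb, a Pax-family homeodomain factor, by -2.91 ± 0.16. The other 9 lowest were CG12520 (-3.14 ± 0.24), CG6472 (-3.10 ± 0.57), Spn28Dc (-2.83 ± 0.36), Pgant2 (-2.81 ± 0.34), CG32206 (-2.79 ± 0.45), Jhbp1 (-2.76 ± 0.13), Mov10 (-2.57 ± 0.29), tty (-2.49 ± 0.49) and CG1494 (-2.39 ± 0.38). Adjusted p was at most 0.0013 for these 24 genes.

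Of 9385 probe sets, 1087 were higher and 970 lower over all depletions, of which 451 and 224 changed at least 2-fold. Probe sets were chosen by mean signal over all 22 arrays, of which 20 are depletion arrays. Genes dim only in GFP thus pass more easily than genes bright only in GFP. The 451 and 224 therefore do not show that large rises outnumber large falls. Leaving out GFP 1 lowered the 2057 calls to 1113. Csl4 2, Dis3 2 and Rrp6 2 deviated together from their groups (residual correlations of 0.306 to 0.411), and without these 3 arrays there were 3364 calls, and between 2971 (Mtr3) and 3646 (Rrp4) for each of Rrp4, Rrp40, Mtr3, Rrp46, Ski6 and Rrp47 against GFP, over 1.5 times the counts given below. In a group of 2 arrays the residuals mirror each other, so the same correlations hold for Csl4 1, Dis3 1 and Rrp6 1. They do not show which array of a group deviated. With the values as deposited the median of all genes shifted by 0.46 and 4089 were higher and 201 lower. All directions here are therefore relative to the bulk of genes on an array, and none of the 24 genes above reversed under any alternative run.

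**Figure D3:**
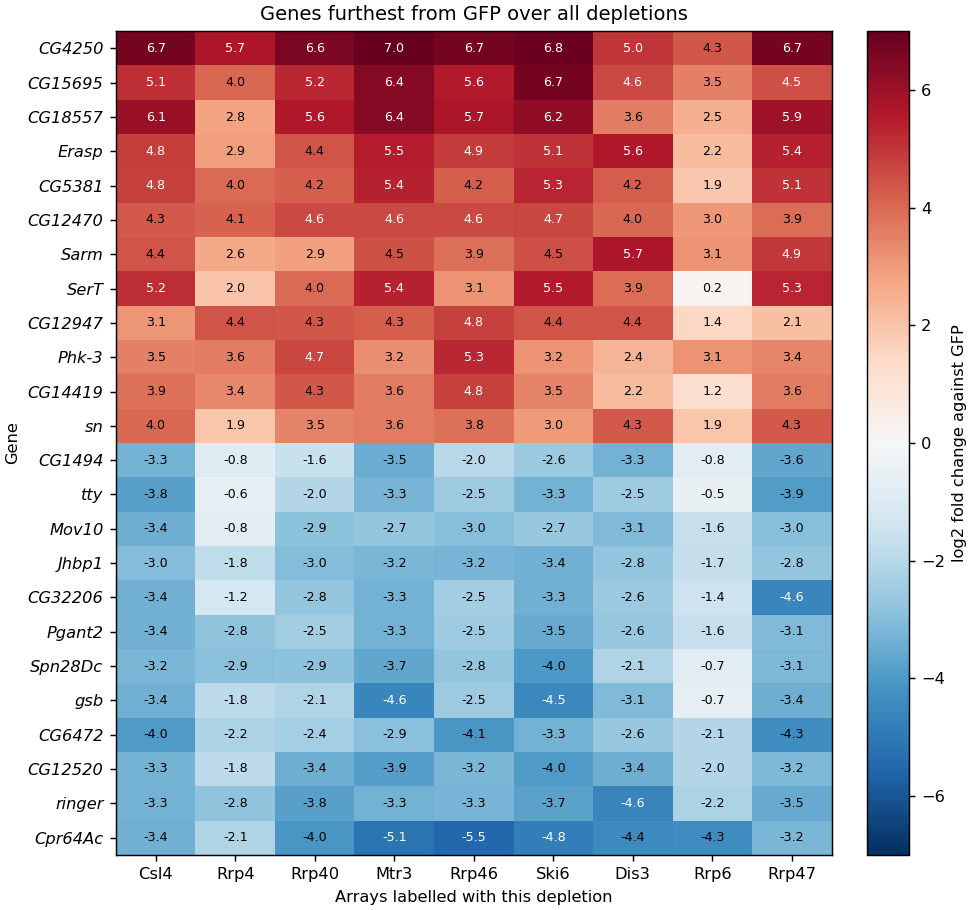
Log2 fold change against GFP (colour) of the 12 highest and 12 lowest named genes over all depletions (rows) in the arrays labelled with each of the 9 depletions (columns). CG4250 ranges from 4.34 in Rrp6 to 7.02 in Mtr3.

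Several lists fixed beforehand moved together over all depletions. Among 17 measured DNA replication genes, 15 rose and 2 did not pass (15 adjusted over the list alone), with PolA1, the catalytic subunit of the DNA polymerase that starts new strands, at 1.69 ± 0.15 and Mcm5, a helicase subunit, at 1.43 ± 0.22. The list's adjusted p was 6.6e-09 (adjusted p = 0.29 with an estimated correlation). Of 13 antimicrobial peptide and immune signalling genes, 12 rose and 1 did not pass (12 adjusted over the list alone). The peptides were Mtk at 2.28 ± 0.32 and Def at 2.04 ± 0.44, and the NF-kappaB factor Rel was at 0.77 ± 0.15 (list adjusted p = 7.1e-09; adjusted p = 0.052 with an estimated correlation). Of 16 mitosis genes, 10 rose, 1 fell and 5 did not pass (11 and 1 adjusted over the list alone). The kinase aurB was at 1.20 ± 0.27 and tum at 1.16 ± 0.23, while Cyclin B (CycB) changed by -0.54 ± 0.11 (list adjusted p = 3.4e-05; adjusted p = 0.39 with an estimated correlation). Without GFP 1, Rel (adjusted p = 0.07) and aurB (0.12) were no longer called, and without GFP 2 neither were Def (0.13) and CycB (0.053). CycB was also not called with the values as deposited (-0.20, adjusted p = 0.28).

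Hemocyte genes, which S2 cells express as blood cell-like cells, went both ways: 9 of 20 rose, 3 fell and 8 did not pass (11 and 3 adjusted over the list alone). PPO1, a prophenoloxidase of the melanizing crystal cells, rose by 4.29 ± 0.22 (19.5-fold), Glt by 3.82 ± 0.25 and the peroxidasin Pxn by 2.97 ± 0.21, whereas hemolectin (Hml) changed by -1.57 ± 0.31 and the integrin ItgaPS4 by -1.82 ± 0.40. The size for PPO1 also rests on a weak GFP signal, with a log2 mean of 2.93. The list's adjusted p was 0.0057 (adjusted p = 0.62 with an estimated correlation), and its call was lost with the values as deposited (0.17) and without GFP 1 (0.078). Without GFP 2 the call of Hml was lost (-1.05, adjusted p = 0.089), and without GFP 1 that of ItgaPS4 (-1.73, adjusted p = 0.062). Of 9 germline genes, 5 rose and 4 did not pass (5 adjusted over the list alone), among them bam, a switch of germ cell differentiation, at 2.27 ± 0.32. AGO3, of the piRNA pathway, was called higher too, but it lay at the floor in both GFP arrays and in 1 of 2 Rrp6 arrays, so its size is not measured. This list's adjusted p was 0.0068 (adjusted p = 0.39 with an estimated correlation), and 0.096 with the values as deposited. Of these 5 lists' members, PolA1, RnrL (1.41 ± 0.15), PCNA (1.38 ± 0.20) and Pxn were called in all 9 depletions, as was Tudor-SN (0.79 ± 0.09) of the small RNA list. Without GFP 1, PCNA was at 0.71 and still called.

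The other 15 lists did not pass over all depletions. Among exosome subunits and cofactors, 1 of 17 rose, Trf4-1, a noncanonical poly(A) polymerase, by 1.42 ± 0.41 (adjusted p = 0.81 for the list). Other mRNA decay factors had 2 of 17 higher, Not3 and Pop2 of the deadenylase complex (0.69 ± 0.15 and 0.47 ± 0.15, list adjusted p = 0.32). Noncoding RNAs and snoRNA hosts had 5 of 22 higher, led by lncRNA:CR43785 at 3.03 ± 0.46 (list adjusted p = 0.34), and JAK-STAT targets 2 of 4, TotC at 2.20 ± 0.43 (at the floor in 1 of 2 GFP arrays) and Stat92E at 0.91 ± 0.24 (list adjusted p = 0.32). The call of Trf4-1 was lost without GFP 2 (1.04, adjusted p = 0.23), and those of Not3 (0.13), Pop2 (0.45), TotC (0.12) and Stat92E (0.36) without GFP 1, with adjusted p in brackets. Oxidative phosphorylation had 6 higher and 1 lower of 58 (adjusted p = 0.069), aminoacyl-tRNA synthetases 1 and 3 of 16 (0.14), with ValRS at -0.75 ± 0.10, endoplasmic reticulum stress 0 and 2 of 11 (0.20) and cytosolic ribosomal proteins 0 and 1 of 37 (0.31). Apoptosis and DNA damage had 1 higher and 1 lower of 12 (0.33), ecdysone response 0 of 8 (0.57), heat shock and chaperones 0 of 8 (0.59), proteasome 2 and 1 of 29 (0.60), mitochondrial ribosomal proteins 4 and 3 of 69 (0.68), small RNA pathway 1 and 1 of 8 (0.80) and ribosome biogenesis 0 of 19 (0.84). The 3 remaining lists had too few measured members for a list test: the 3 histone probe sets each carried several symbols, so none stood for 1 gene, and neither the 2 measured neuronal markers (elav, brp) nor the 1 muscle marker (Prm) was called over all depletions. Across the 280 list tests, 85 were called with the preset correlation, 0 by camera with an estimated correlation and 104 by fry. Of the 85, 60 were also called with the values as deposited, 79 with median centring, 77 without GFP 1 and 81 without GFP 2.

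**Figure D4:**
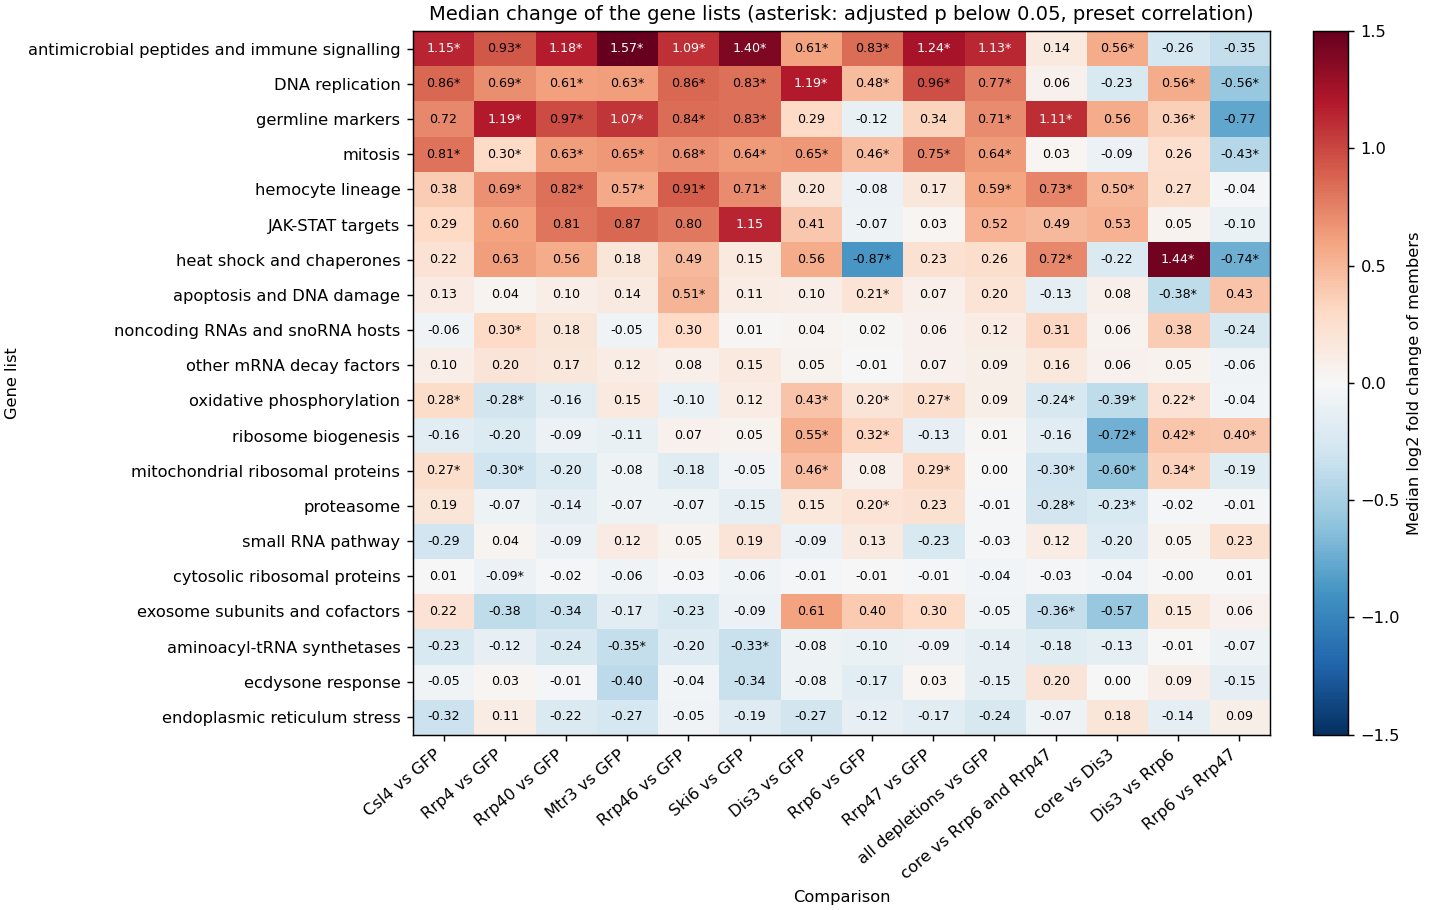
Median log2 fold change of the measured members (colour) of the 20 tested lists (rows) in the 14 comparisons (columns), with an asterisk where adjusted p was under 0.05 at the preset correlation. DNA replication and immune genes carry an asterisk in each of the 9 depletions against GFP.

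In the arrays labelled Csl4, CG4250 (6.68 ± 0.26), CG18557 (6.07 ± 0.27), CG4793 (5.48 ± 0.74), CG33462 (5.35 ± 0.38) and nau, the fly MyoD homologue (5.25 ± 0.82), were highest. The lowest genes were Ccn (-4.70 ± 0.67), myofilin (Mf, -4.32 ± 0.56), the Ras regulator raskol (-4.15 ± 0.58), CG6472 (-3.96 ± 0.76) and tty (-3.79 ± 0.66). DNA replication had 11 of 17 genes higher (13 adjusted over the list alone), with PolA1 at 1.82 and Mcm2 at 1.75 (list adjusted p = 5e-08; adjusted p = 0.31 with an estimated correlation). Immune genes had 11 of 13 higher (12 adjusted over the list alone), with Mtk at 2.77 and Drs at 2.25 (2.5e-07; adjusted p = 0.075 with an estimated correlation). On these arrays the 18S control signal lay 2.29 (log2) above GFP. There were 862 higher and 880 lower probe sets, 1697 and 312 with the values as deposited. The 1742 calls became 1042 without Csl4 2 and 559 when only the Csl4 and GFP arrays were fitted. Ccn and raskol lay at the floor in 1 of 2 Csl4 arrays, and Ccn only 0.11 above it in the other, so neither size is fully measured. Without Csl4 1, CG6472 was at -2.57 and still called.

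The genes furthest above GFP in arrays labelled Rrp4 were CG4250 (5.68 ± 0.23), CG12535 (5.22 ± 0.29), PPO1 (5.14 ± 0.25) and CG42331 (5.09 ± 0.67). AGO3, at the floor in both GFP arrays, was higher by at least 4.84. The lowest were CG15096 (-3.12 ± 0.61), the serpin Spn28Dc (-2.92 ± 0.42), ringer (-2.84 ± 0.26), Pgant2 (-2.79 ± 0.40) and CG11378 (-2.29 ± 0.47). Hemocyte genes had 8 of 20 higher (8 adjusted over the list alone; list adjusted p = 0.00011; adjusted p = 0.49 with an estimated correlation). Noncoding RNAs had 8 of 22 higher (9 adjusted over the list alone; 0.033; adjusted p = 0.31 with an estimated correlation), with lncRNA:CR43785 at 2.26 and asRNA:CR43964 at 2.20. Mitochondrial ribosomal proteins had 10 of 69 lower (7 adjusted over the list alone; 0.00029; adjusted p = 0.79 with an estimated correlation), with mRpL52 at -1.28, although with the values as deposited mRpL52 was at 0.39 and their median went from -0.30 to 1.35. There were 1176 higher and 1059 lower probe sets, 8797 and 7 as deposited (median shift 1.58) and 978 and 1347 with median centring. These 4 arrays had the spike-in signals given above, and the 2235 calls became 1075 without GFP 1, 1319 with Rrp4 1 and 2 alone and 1340 with Rrp4 3 and 4 alone. Calls were lost for noncoding RNAs without GFP 2 (adjusted p = 0.076), and for CG11378 (-1.99, adjusted p = 0.051) and lncRNA:CR43785 (1.33, adjusted p = 0.18) without GFP 1.

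Arrays labelled Rrp40 were highest for CG4250 (6.57 ± 0.26), CG43336 (5.94 ± 0.76), PPO1 (5.79 ± 0.29), CG18557 (5.58 ± 0.27) and CG15695 (5.25 ± 0.48). They were lowest for CG15096 (-4.97 ± 0.70, at the floor in 1 of 2 Rrp40 arrays), Cpr64Ac (-4.05 ± 0.79), ringer (-3.77 ± 0.29), CG12520 (-3.43 ± 0.33) and CG6661 (-3.07 ± 0.67). Germline genes had 5 of 9 higher (5 adjusted over the list alone), with AGO3 higher by at least 4.61 (both GFP arrays at the floor) and the piRNA scaffold tud at 2.17 (list adjusted p = 0.0066; adjusted p = 0.39 with an estimated correlation). There were 1020 higher and 886 lower probe sets. The 1906 calls became 1068 without GFP 1 (which ended the call of tud, adjusted p = 0.076), 881 without Rrp40 1 and 1116 without Rrp40 2.

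For Mtr3, the 5 highest named genes were CG4250 (7.02 ± 0.26), CG15695 (6.44 ± 0.48), CG18557 (6.37 ± 0.27), CG4793 (6.29 ± 0.74) and CG3117 (5.65 ± 0.38, at the floor in 1 of 2 GFP arrays). The 5 lowest were CG10163 (-5.67 ± 0.55), Cpr64Ac (-5.12 ± 0.79), gsb (-4.59 ± 0.22), the peptidase Ance (-3.97 ± 0.27) and CG12520 (-3.88 ± 0.33). Hemocyte genes had 10 of 20 higher and 2 lower (11 and 2 adjusted over the list alone), with Glt at 5.49 and Pxn at 4.29 against -2.07 for Hml and -2.63 for ItgaPS4 (list adjusted p = 0.0003; adjusted p = 0.51 with an estimated correlation). Aminoacyl-tRNA synthetases had 5 of 16 lower (5 adjusted over the list alone), with ValRS at -1.14 (0.022; adjusted p = 0.51 with an estimated correlation), but their median went from -0.35 to 0.47 with the values as deposited. On these arrays the 18S control signal lay 3.92 (log2) above GFP. There were 942 higher and 831 lower probe sets, 6586 and 104 as deposited (median shift 0.97) and 751 and 1166 with median centring. The 1773 calls became 1098 without GFP 1 (which also ended the synthetase call, adjusted p = 0.088), 974 without Mtr3 2 and 1115 when only the Mtr3 and GFP arrays were fitted.

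Rrp46 arrays rose furthest above GFP for CG4250 (6.71 ± 0.26), PPO1 (6.00 ± 0.29), CG18557 (5.70 ± 0.27), CG15695 (5.57 ± 0.48) and CG43336 (5.56 ± 0.76). They lay furthest below it for Cpr64Ac (-5.50 ± 0.79), CG15096 (-5.08 ± 0.70), Pepck2, a phosphoenolpyruvate carboxykinase (-4.90 ± 0.51, at the floor in 1 of 2 Rrp46 arrays), CG6472 (-4.10 ± 0.76) and Vago (-3.48 ± 0.59). DNA replication had 10 of 17 genes higher (12 adjusted over the list alone), with RnrL, of ribonucleotide reductase, at 2.13 (list adjusted p = 6.8e-08; adjusted p = 0.31 with an estimated correlation). There were 988 higher and 868 lower probe sets, 983 and 399 as deposited. The 1856 calls became 1007 without GFP 1, 973 without Rrp46 1 and 940 without Rrp46 2.

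Against GFP, the Ski6 arrays were highest for CG4250 (6.84 ± 0.26), CG15695 (6.71 ± 0.48), CG18557 (6.22 ± 0.27), CG4793 (5.83 ± 0.74) and Nazo (5.55 ± 0.68). They were lowest for CG10163 (-5.66 ± 0.55), Cpr64Ac (-4.83 ± 0.79), gsb (-4.52 ± 0.22), Pepck2 (-4.34 ± 0.51, at the floor in 1 of 2 Ski6 arrays) and Spn28Dc (-4.02 ± 0.49). Immune genes had 12 of 13 higher (12 adjusted over the list alone), with Mtk at 3.17 and Def at 2.92 (list adjusted p = 7.1e-09; adjusted p = 0.052 with an estimated correlation), beside an 18S control signal 4.63 (log2) above GFP. There were 1126 higher and 1009 lower probe sets, 6784 and 112 as deposited (median shift 1.02) and 907 and 1357 with median centring. The 2135 calls became 1249 without GFP 1, 1202 without Ski6 1 and 1273 without Ski6 2. Nazo differed between the GFP arrays, and its size was 3.69 without GFP 1 and 7.41 without GFP 2, called both times.

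In the arrays labelled Dis3, Sarm (5.66 ± 0.40), Erasp (5.60 ± 0.54), CG33462 (5.11 ± 0.38), CG7299 (5.05 ± 0.71) and CG4250 (4.99 ± 0.26) were highest. The lowest genes were ringer (-4.62 ± 0.29), Cpr64Ac (-4.44 ± 0.79), Hml (-4.33 ± 0.42), CG10163 (-4.29 ± 0.55) and Acer (-3.67 ± 0.85, at the floor in 1 of 2 Dis3 arrays). Of 19 ribosome biogenesis genes, 9 were higher and 1 lower (12 and 1 adjusted over the list alone), with the nucleolar methyltransferase Fib at 1.47 (list adjusted p = 9.9e-05; adjusted p = 0.29 with an estimated correlation). Oxidative phosphorylation had 22 of 58 higher (30 adjusted over the list alone), with ATPsynC at 1.61 (1.6e-07; adjusted p = 0.59 with an estimated correlation), and mitochondrial ribosomal proteins 20 higher and 3 lower of 69 (27 and 3 adjusted over the list alone; 2.6e-06; adjusted p = 0.73 with an estimated correlation). The 18S control signal was 4.69 above GFP on these arrays. There were 1029 higher and 960 lower probe sets, 577 and 1143 as deposited, and the 1989 calls became 399 when only the Dis3 and GFP arrays were fitted and 778 with array weights. Acer was no longer called without Dis3 2 (-2.01, adjusted p = 0.092) or GFP 2 (-3.11, adjusted p = 0.054).

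Rrp6 arrays were highest for the cytochrome P450 Cyp6d2 (4.85 ± 0.69), the odorant-binding protein gene Obp28a (4.82 ± 0.66), CG4250 (4.34 ± 0.26), 18SrRNA-Psi:CR41602, an 18S ribosomal RNA pseudogene (4.33 ± 0.38), and CG15695 (3.55 ± 0.48), beside an 18S control signal 4.42 above GFP. Cpr64Ac (-4.33 ± 0.79), the neuropeptide gene CNMa (-3.62 ± 0.64), CG5697 (-3.50 ± 0.31), superdeath (-3.24 ± 0.28) and Fie (-3.17 ± 0.50, at the floor in 1 of 2 Rrp6 arrays) were lowest. Without Rrp6 2, Cpr64Ac was at -2.75 and CNMa at -2.09, both still called. Apoptosis and DNA damage genes had 5 of 12 higher (5 adjusted over the list alone), with the DNA repair genes Ku80 at 1.11 and mre11 at 1.08 (list adjusted p = 0.0055; adjusted p = 0.13 with an estimated correlation). Heat shock genes had 1 of 8 lower, stv at -2.23 (3 adjusted over the list alone; 0.0068; adjusted p = 0.62 with an estimated correlation), a list call lost without GFP 1 (0.6). The call of stv was lost without GFP 1 (-0.90, adjusted p = 0.28) and without Rrp6 1 (-1.67, adjusted p = 0.1), while without GFP 2 it was at -3.57. There were 401 higher and 427 lower probe sets, 177 and 528 as deposited. The 828 calls became 37 when only the Rrp6 and GFP arrays were fitted, 138 with array weights, 511 without GFP 1 and 1578 without Rrp6 1.

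Highest in the arrays labelled Rrp47 were CG4250 (6.72 ± 0.26), CG18557 (5.93 ± 0.27), PPO1 (5.58 ± 0.29), Erasp (5.39 ± 0.54) and SerT (5.31 ± 0.15). Lowest were CG15096 (-5.99 ± 0.70), raskol (-4.59 ± 0.58), CG32206 (-4.56 ± 0.60), CG6472 (-4.35 ± 0.76) and tty (-3.93 ± 0.66). Mitosis genes had 9 of 16 higher and 1 lower (13 and 1 adjusted over the list alone), with aurB at 1.81 and tum at 1.72 against -0.63 for CycB (list adjusted p = 5e-05; adjusted p = 0.39 with an estimated correlation). On these arrays the 18S control signal lay 1.58 (log2) above GFP. There were 965 higher and 955 lower probe sets, 3889 and 193 as deposited (median shift 0.59). The 1920 calls became 954 without Rrp47 1 and 1033 without Rrp47 2. The call of CycB was lost without GFP 2 (adjusted p = 0.061), without Rrp47 2 (0.057) and with the values as deposited (-0.16, adjusted p = 0.55).

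**Figure D5:**
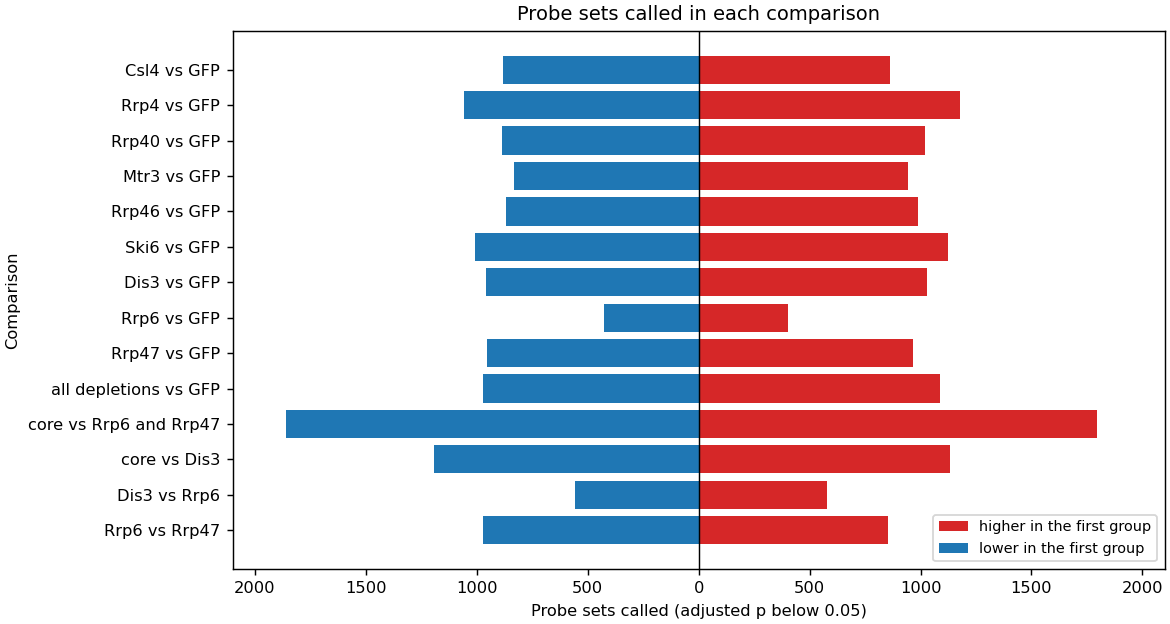
Number of probe sets called higher and lower (horizontal axis) in each comparison (vertical axis), of 9385 tested. The lowest number against GFP is that of Rrp6, with 401 higher and 427 lower.

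Against GFP, part of the changes were shared: 93 probe sets were higher and 57 lower in all 9 depletions. In 100 simulations of unchanged groups against the same 2 controls, the highest number shared by 4 or more groups was 0. These simulations held no offset of the 2 GFP arrays as a set, which would appear in all 9 comparisons. Shared calls therefore cannot be told apart from such an offset. Fold changes against GFP correlated across genes between depletions at r of 0.28 to 0.947, with a median of 0.67 over 36 pairs. Simulated without changes, the shared controls alone gave r of 0.498 to 0.503, and of 0.576 to 0.579 for pairs with Rrp4. In 10 of the 36 pairs r lay below this value, among them 7 of the 8 pairs with Rrp6 (0.28 for Rrp4 and Rrp6) and 4 of the 8 with Rrp4, while the covariance lay above its simulated value in all 36. Genes are not independent replicates, so no p is attached. The 150 shared calls became 29 with array weights and 67 with the values as deposited.

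Depletions also differed from each other, in 5417 of 9385 probe sets by the F test, 2705 without the Rrp4 arrays and 9062 with the values as deposited. Against the other 8 depletions, Rrp6 arrays were higher for Cyp6d2 (3.56 ± 0.52), Ance (3.36 ± 0.20) and CG15096 (3.34 ± 0.53) and lower for PPO1 (-5.28 ± 0.22), CG33462 (-4.96 ± 0.28) and CG43336 (-4.58 ± 0.56). Dis3 arrays were higher for CG7299 (4.83 ± 0.53), CG16713 (2.75 ± 0.64) and the adhesion gene kirre (2.68 ± 0.47) and lower for the homeobox gene mirr (-4.23 ± 0.30), nau (-3.83 ± 0.61) and CG40160 (-3.50 ± 0.48). Rrp4 arrays were higher for Pepck2 (4.06 ± 0.28), CG10163 (3.36 ± 0.31) and CG5697 (2.77 ± 0.17) and lower for CG7299 (-3.16 ± 0.40), Nazo (-2.99 ± 0.38) and CG44014 (-2.42 ± 0.11). Rrp47 arrays were higher for Rrp47, Nha2 (1.86 ± 0.41) and lncRNA:CR43785 (1.71 ± 0.46) and lower for Nhe2 (-3.13 ± 0.44), CG11313 (-3.05 ± 0.49) and raskol (-3.05 ± 0.43). Against the other 8 there were 2399 calls for Rrp6 (1453 without Rrp6 2), 1808 for Dis3 (692 without Dis3 2) and 1886 for Rrp47 (19 without Rrp47 1, 109 without Rrp47 2, 2869 without Dis3 2 and 2957 without Rrp6 2). Rrp4, with 4 arrays against 2, had 3376, and 1184 to 1671 with any 2 of them. Without Rrp47 1, the calls of Nha2 (0.17), lncRNA:CR43785 (0.21), Nhe2 (0.064), CG11313 (0.055) and raskol (0.073) were lost, with adjusted p in brackets. Without Rrp47 2 those of Nha2, lncRNA:CR43785 and CG11313 were lost, and without Dis3 2 that of CG16713 (0.12), with nau at -1.98 and still called. Some of these sizes include arrays at the floor: 1 of 2 Rrp6 arrays for CG43336 and CG16713, 1 of 2 Rrp40 arrays for CG15096, 1 of 4 Rrp4 and 1 of 2 Rrp46 arrays for CG7299, 1 of 2 Rrp46 and 1 of 2 Ski6 arrays for Pepck2, and 1 of 2 Csl4 arrays for raskol.

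The remaining groups had fewer calls against the other 8, from 196 for Rrp46 to 511 for Ski6, though without 1 array these counts ranged from 20 (Rrp46, without Rrp46 2) to 1089 (Csl4, without Dis3 2). Among the named genes whose call held without any 1 array, Ski6 arrays were higher for trol, the basement membrane perlecan (2.85 ± 0.29), and lower for CG10163 (-2.80 ± 0.41), and Mtr3 arrays were higher for dmGlut, a glutamate transporter (2.27 ± 0.34, at the floor in 1 of 2 Rrp6 arrays), and lower for gsb (-1.89 ± 0.17). Rrp46 arrays were higher for CG6345 (4.48 ± 0.44) and PPO1 (1.93 ± 0.22) and lower for Pepck2 (-3.10 ± 0.38, at the floor in 1 of 2 Rrp46 and 1 of 2 Ski6 arrays), Rrp40 arrays were lower for CG42675 (-2.41 ± 0.24), and Csl4 arrays were lower for Mf (-2.97 ± 0.42). By direct comparison 1 probe set differed between Mtr3 and Ski6, 3 between Csl4 and Rrp47, 13 between Rrp40 and Rrp46, and 3727 between Rrp4 and Rrp47.

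The core class was compared with Rrp6 and Rrp47 to set the ring and cap against the nuclear exonuclease and its partner. Core arrays were higher for Cyp4ac2, a cytochrome P450 (2.72 ± 0.41), sli, the secreted guidance cue Slit (2.67 ± 0.70), mirr (2.66 ± 0.23), CG12947 (2.47 ± 0.40) and CG6357 (2.42 ± 0.36). Of these, sli and CG6357 lay at the floor in 1 of 2 Rrp6 arrays, and sli also in 1 of 2 Csl4 arrays. They were lower for Cyp6d2 (-1.96 ± 0.39), CG32212 (-1.85 ± 0.48), Ance (-1.77 ± 0.15), CG8620 (-1.74 ± 0.22) and Dora (-1.52 ± 0.51). Of 20 hemocyte genes, 14 were higher and 1 lower (14 and 2 adjusted over the list alone), with PPO1 at 2.31 ± 0.17 and the phagocytic receptor eater at 2.16 ± 0.25 (list adjusted p = 2.2e-06; adjusted p = 0.37 with an estimated correlation). Of 9 germline genes, 7 were higher (8 adjusted over the list alone), with AGO3 at 2.14 ± 0.26 (at the floor in 1 of 2 Rrp6 arrays) and aub at 1.88 ± 0.31 (0.00021; adjusted p = 0.29 with an estimated correlation). Of 8 heat shock genes, 6 were higher (6 adjusted over the list alone; 0.0065; adjusted p = 0.62 with an estimated correlation). Mitochondrial ribosomal proteins were lower in 30 of 69 (33 adjusted over the list alone; 2.1e-05; adjusted p = 0.75 with an estimated correlation), but their median turned to 0.21 with the values as deposited. Proteasome genes were lower in 17 of 29 with 1 higher (17 and 2 adjusted over the list alone; 0.002; adjusted p = 0.51 with an estimated correlation), with a median of 0.12 as deposited. Exosome genes were lower in 8 of 17 with 2 higher (9 and 2 adjusted over the list alone; 0.041; adjusted p = 0.67 with an estimated correlation), with a median of 0.19 as deposited. These counts include the targeted genes, and the call of the exosome list was lost without the 9 targets (adjusted p = 0.09, 6 of 8 lower and 1 higher) and with median centring (0.091).

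Rrp6 and Rrp47 lay apart within this class. Of the 3653 calls, 630 were also called the same way against Rrp6 alone and against Rrp47 alone, 1510 against Rrp6 only, 1078 against Rrp47 only and 435 against neither, in tests added after the main result was seen. PPO1 was 5.30 ± 0.22 above Rrp6 in the core but 0.68 ± 0.22 below Rrp47 (adjusted p = 0.033). Cyp6d2 differed from the core in Rrp6 (core lower, -3.91 ± 0.52) and not in Rrp47 (-0.01 ± 0.52), and CG6357 by 4.89 ± 0.48 and -0.05 ± 0.48. Cyp4ac2, mirr, Ance, CG8620, CG32212, eater, AGO3 and aub also passed against Rrp6 only. CG12947 passed against both (2.79 ± 0.53 and 2.14 ± 0.53), sli against Rrp47 only (2.99 ± 0.93) and Dora against neither.

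In this comparison 1794 probe sets were higher and 1859 lower, 5385 and 81 as deposited (median shift 0.45) and 1454 and 2438 with median centring. With the subunit as a random block, so that subunits and not arrays are the replicates, the 3653 calls became 169, and leaving out Rrp6 2 or Rrp47 1 gave 1613 and 2095. Without Rrp6 2, sli (1.89, adjusted p = 0.092), CG32212 (-1.69, adjusted p = 0.052) and Dora (-1.31, adjusted p = 0.14) were no longer called, nor were sli (adjusted p = 0.056) and Dora (adjusted p = 0.095) without Rrp47 1, or Dora without Rrp47 2 (adjusted p = 0.066).

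Against Dis3, the core class was higher for mirr (4.89 ± 0.31), nau (4.08 ± 0.62), CG40160 (3.77 ± 0.49), CG15543 (3.42 ± 0.57) and Hml (3.38 ± 0.32). It was lower for CG7299 (-4.97 ± 0.54, at the floor in 1 of 4 Rrp4 and 1 of 2 Rrp46 arrays), Cyp6d2 (-2.86 ± 0.53), kirre (-2.81 ± 0.48), CG9098 (-2.60 ± 0.39) and CG16713 (-2.49 ± 0.65). Mitochondrial ribosomal proteins were lower in 46 of 69 with 1 higher (56 and 1 adjusted over the list alone; list adjusted p = 1.3e-11; adjusted p = 0.59 with an estimated correlation), yet their median turned to 0.24 with the values as deposited. Oxidative phosphorylation genes were lower in 32 of 58, with a median of 0.46 as deposited (37, with 1 higher, adjusted over the list alone; 6.6e-09; adjusted p = 0.51 with an estimated correlation), among them ATPsynC at -0.98 ± 0.11. Ribosome biogenesis genes were lower in 13 of 19, with a median of 0.12 as deposited (15, with 1 higher, adjusted over the list alone; 1.3e-07; adjusted p = 0.089 with an estimated correlation). Immune genes were higher in 8 of 13 (8 adjusted over the list alone), with DptB at 1.91 ± 0.31 and Mtk at 1.88 ± 0.32 (0.0025; adjusted p = 0.31 with an estimated correlation). In all, 1135 probe sets were higher and 1191 lower, 7214 and 67 as deposited (median shift 0.88). The 2326 calls became 768 without Dis3 2 (which ended the call of CG16713, adjusted p = 0.18, and left nau at 2.24, called), 723 with array weights and 1402 without Csl4 2, Dis3 2 and Rrp6 2.

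Between the exonucleases, Dis3 arrays were higher than Rrp6 arrays for CG7299 (5.22 ± 0.71), CG33462 (5.09 ± 0.38), CG16713 (4.83 ± 0.86, at the floor in 1 of 2 Rrp6 arrays), PPO1 (4.41 ± 0.29) and Ugt37D1 (4.15 ± 0.43). They were lower for CG45263 (-3.69 ± 0.31), Ance (-3.45 ± 0.27), Hml (-3.11 ± 0.42), CG9168 (-2.93 ± 0.59) and CG10953 (-2.88 ± 0.27). Heat shock genes were higher in 5 of 8 (6 adjusted over the list alone), with stv at 3.30 ± 0.58 and Hsp68 at 2.49 ± 0.57 (list adjusted p = 8.3e-05; adjusted p = 0.41 with an estimated correlation). Apoptosis and DNA damage genes were lower in 4 of 12 (4 adjusted over the list alone), with Irbp18 at -0.96 ± 0.17 and mre11 at -0.72 ± 0.15 (0.025; adjusted p = 0.29 with an estimated correlation). There were 580 higher and 559 lower probe sets. The 1139 calls became 11 when only these 4 arrays were fitted and 118 with array weights, and that of Hsp68 was lost without Rrp6 1 (1.44, adjusted p = 0.11), when CG16713 was at 2.93 and still called.

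Rrp6 arrays were higher than Rrp47 arrays for CG15096 (5.48 ± 0.70), raskol (5.45 ± 0.58), CG15347 (3.95 ± 0.28), CG45263 (3.92 ± 0.31) and Cyp6d2 (3.91 ± 0.69). They were lower for PPO1 (-5.98 ± 0.29), CG33462 (-5.28 ± 0.38), SerT (-5.12 ± 0.15), CG43336 (-4.99 ± 0.76) and CG6357 (-4.94 ± 0.63), the last 2 at the floor in 1 of 2 Rrp6 arrays. Ribosome biogenesis genes were higher in 8 of 19 (9, with 1 lower, adjusted over the list alone; list adjusted p = 0.0027; adjusted p = 0.39 with an estimated correlation), although their median went from 0.40 to -0.34 with the values as deposited. DNA replication genes were lower in 6 of 17 with 1 higher (8 and 2 adjusted over the list alone), with Mcm5 at -1.10 ± 0.30 and RPA1 at 0.90 ± 0.12 (0.048; adjusted p = 0.73 with an estimated correlation). There were 853 higher and 971 lower probe sets, 138 and 4952 as deposited (median shift -0.76). The 1824 calls became 336 when only these 4 arrays were fitted, 969 without Rrp47 1, 1018 without Rrp47 2 and 3392 without Csl4 2, Dis3 2 and Rrp6 2. Mcm5 was no longer called without Rrp6 1 (-0.35, adjusted p = 0.24), Rrp47 1 (adjusted p = 0.074) or Rrp47 2 (adjusted p = 0.088), and was at -1.84 without Rrp6 2.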

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

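The tests on the targeted genes, on pairs of depletions, on the handling of the Rrp4 arrays, on pairs with Rrp4 and on choices of 2 subunits of 2 arrays each were chosen after the results were seen, while those on the number of Rrp4 arrays, on splits of the samples and on choices of any 2 subunits were written down beforehand.

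Differences between depletions were marked for a closer look because a test of the difference itself passed: 5417 probe sets differed among the 9 depletions (2705 without the Rrp4 arrays, 9062 with the values as deposited), 3653 between the core class and Rrp6 with Rrp47, 2326 between the core class and Dis3, 1139 between Dis3 and Rrp6 and 1824 between Rrp6 and Rrp47. Of the 24 named genes of all depletions against GFP, 23 differed among depletions, the exception being CG6472 (adjusted p = 0.056). Data outside the comparisons were marked too: the 18S ribosomal RNA control signal (log2) of both arrays lay above both GFP arrays in Csl4 (2.29 above the GFP mean), Mtr3 (3.92), Ski6 (4.63), Dis3 (4.69), Rrp6 (4.42) and Rrp47 (1.58). There were also 2 control probe sets with signals of at least 977.7 in both GFP arrays and at most 22.26 in the other 20. The calls of the core class against Rrp6 and Rrp47 became 1613 without Rrp6 2 and 2095 without Rrp47 1, those against Dis3 768 without Dis3 2, and those of Rrp6 against Rrp47 969 without Rrp47 1 and 1018 without Rrp47 2.

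The first pattern is that 4 of the 9 targeted genes were higher in the arrays of their own depletion, by 1.71 to 2.68 (log2). A rise of the exosome genes as a set is argued against, since the other targets had a median of -0.025 over 72 values (quartiles -0.366 and 0.319), with 2 called higher and 2 lower. Probe sets that detect the dsRNA itself may account for the rise, and the 2 control probe sets bright only in GFP arrays could be of that kind, but the tables used here do not say what they match, so this cannot be told apart from a response of the gene. Wrong labels are argued against for the groups of the 4 raised genes. Both own arrays of each gene lay above all other arrays. Against the other 8 depletions, the 4 genes were higher by 1.97 to 2.59 (log2, SE 0.17 to 0.24). As many targets were highest in their own group in a share of 0.01 of 100000 random assignments. That count restates the pattern and says nothing of the other 5 groups. There wrong labels stay open, although Dis3 (-1.25 ± 0.24) and Rrp6 (-0.87 ± 0.20) were lower in their own arrays than in the other 8 depletions. A response of the targeted gene to its own depletion was not tested.

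The second pattern is that some depletions differed from each other by few probe sets (1 for Mtr3 and Ski6, 3 for Csl4 and Rrp47, 13 for Rrp40 and Rrp46). Arrays handled together may account for it: over 28 pairs of the 8 depletions with 2 arrays, distance in deposited brightness, spike-in and 18S signal rose with the number of probe sets called (Pearson r = 0.393, one-sided exact permutation p = 0.021; Spearman rho = 0.355, p = 0.04). Without Rrp40 and Rrp6, the depletions farthest from the median distance, r was 0.439 (exact permutation p = 0.071 over 15 pairs), and none of brightness (r = 0.169), spike-in (0.259) or 18S (-0.021) passed alone. Place in the complex could account for it as well: among the 8 depletions with 2 arrays, which leaves out Rrp4, pairs within the core differed by a mean of 225 probe sets and pairs of a core subunit with Dis3, Rrp6 or Rrp47 by 1523.4, a difference of 1298.4 (exact permutation p = 0.018). With Rrp4 and its 4 arrays the means were 586.1 and 1848.6 (exact permutation p = 0.012), although Csl4 and Rrp47 are a mixed pair with few calls. The distance used above does not isolate handling, since the depletions could themselves change 18S signal or brightness. Both explanations remain open.

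The third pattern is that Rrp4 arrays differed most from the other 8 depletions, in 3376 probe sets. The number of arrays may explain the rank: with any 2 of the 4 Rrp4 arrays the count was 1184 to 1671, with a median of 1432, against 2399 for Rrp6 (1453 without Rrp6 2). Handling apart cannot be told apart from the depletion, because these arrays alone carry the separate scaling and a spike-in signal 3.254 (log2) below the lowest other array, and no other group shares it. A biological difference of Rrp4 stays open and was not tested.

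Other splits of the arrays were fitted with 2 classes. For the core class against Rrp6 and Rrp47, 1 of 100 splits of the 18 arrays into 14 and 4, the real one, gave as many probe sets (2250, highest other 2). For Rrp4 against the other 8, 2 of 100 splits of the 20 arrays into 4 and 16 gave as many as the real 1388. Nearly all random splits part the arrays of a subunit, which the real splits keep together (1 and 0 of the other 99 did so), so these counts do not decide whether chance can be excluded. The highest other split of the 20, with 3436, set Dis3 2, Rrp6 2, Rrp47 1 and Rrp47 2 against the rest, which points to a structure of the samples. With subunits kept together, 2 of the 21 choices of 2 subunits of 2 arrays each gave as many as the real 2250, the other being Csl4 with Rrp47 at 2801. In the main fit, 2 of the 28 choices of any 2 of the 8 subunits gave as many as the real 3653, again with Csl4 and Rrp47 (3916), so chance is not excluded and this class is not singled out.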

How the results depend on the processing

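Alternatives that left out all Rrp4 arrays, pairs of them, Csl4 2, Dis3 2 and Rrp6 2 together, or the 9 target probe sets were chosen after seeing the data. Without the target probe sets, 84 of the 280 list tests were called. All counts and target levels stayed within 1.5 times, or on the same side of the threshold and in the same direction, with median centring, no floor, an offset of 50, and 1 probe set per gene. Called list members were added to the gene checks after the main results were seen. For named genes other than the targets in their own arrays, 9761 of 10493 alternative values kept direction and call, 713 kept direction but lost the call, and 19 reversed; 198 of 450 results had any such change. Of calls against GFP, 41.5% to 78.8% were called again without 1 GFP array, all in the same direction. Signal over background limits probe sets near the floor, and 9385 of 18769 probe sets were bright enough to be tested. Where calls fell with a stricter threshold or fold minimum, fewer tested probe sets, or fewer arrays, the alternative's construction shows why; for the rest the cause was not tested.

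With the values as deposited, counts were 4290 for all depletions, 8804 for Rrp4, 6690 for Mtr3, 6896 for Ski6, 4082 for Rrp47, 7281 for core against Dis3, 739 for Dis3 against Rrp6, 5090 for Rrp6 against Rrp47, 9062 among depletions, 9282 for one depletion against the other 8 and 67 shared calls; the Mtr3 target was at 1.61 and called, and the Rrp4 target reversed to 1.04, uncalled. With a filter at the 75th percentile of signal, counts were 1305 (all depletions), 1114 (Csl4), 1144 (Mtr3), 1204 (Rrp40), 1179 (Rrp46), 1403 (Ski6), 512 (Rrp6), 751 (Dis3 against Rrp6), 1166 (Rrp6 against Rrp47), 3941 (one against the other 8) and 90 (shared). Array weights gave 927 (Csl4), 778 (Dis3), 138 (Rrp6), 723 (core against Dis3), 118 (Dis3 against Rrp6), 936 (Rrp6 against Rrp47) and 29 (shared). At least 2-fold changes numbered 675 (all depletions), 855 (Csl4), 753 (Rrp4), 887 (Rrp40), 893 (Mtr3), 898 (Rrp46), 1022 (Ski6), 916 (Dis3), 418 (Rrp6), 913 (Rrp47), 457 (core against Rrp6 and Rrp47), 532 (core against Dis3), 510 (Dis3 against Rrp6), 870 (Rrp6 against Rrp47), 1546 (one against the other 8) and 66 (shared). An adjusted p under 0.01 gave 1273 (all depletions), 965 (Csl4), 1094 (Rrp4), 954 (Rrp40), 1027 (Mtr3), 960 (Rrp46), 1237 (Ski6), 1134 (Dis3), 354 (Rrp6), 989 (Rrp47), 1899 (core against Rrp6 and Rrp47), 1224 (core against Dis3), 553 (Dis3 against Rrp6), 987 (Rrp6 against Rrp47), 3183 (among depletions), 3361 (one against the other 8) and 66 (shared).

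The Dis3 target (-1.17) lost its call with array weights, an adjusted p under 0.01 and only the groups compared, and at -0.82 without Csl4 2, Dis3 2 and Rrp6 2. The Rrp6 target (-0.91) lost its call with no filter, no trend, array weights, an adjusted p under 0.01 and only the groups compared, and at -0.90 without all Rrp4 arrays; over all its alternatives, adjusted p ranged up to 0.56. With replicate number as a block, although the numbers do not pair the arrays across groups in general, Rrp4 had 1199 calls. The Rrp4 target then reversed to 0.79, uncalled, and the Rrp6 target was not called at -0.91. Rrp4 1 and 2 alone gave 1319 calls and a target at 0.80, reversed and uncalled, and Rrp4 3 and 4 alone 1340 and -1.999, called.

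Fits of only the groups compared gave 559 (Csl4), 1115 (Mtr3), 399 (Dis3), 37 (Rrp6), 11 (Dis3 against Rrp6) and 336 (Rrp6 against Rrp47). With the subunit as a random block (correlation 0.485), core against Rrp6 and Rrp47 had 169 calls, and 2372 at an unadjusted p under 0.05. Without all Rrp4 arrays, 2705 differed among depletions and 3095 in one against the other 8. Without Csl4 2, Dis3 2 and Rrp6 2, counts were 3364 (all depletions), 3646 (Rrp4), 3298 (Rrp40), 2971 (Mtr3), 3166 (Rrp46), 3324 (Ski6), 3315 (Rrp47), 1402 (core against Dis3) and 3392 (Rrp6 against Rrp47). With an estimated correlation, 0 of the 85 list calls passed, against 104 by fry, 70 of them among the 85.

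Leaving out 1 array at a time, counts ranged from 1113 (without GFP 1) to 2377 for all depletions, 1042 (Csl4 2) to 2022 for Csl4, 1075 (GFP 1) to 2664 for Rrp4, 881 (Rrp40 1) to 2305 for Rrp40, 974 (Mtr3 2) to 2104 for Mtr3, 940 (Rrp46 2) to 2181 for Rrp46, 1202 (Ski6 1) to 2502 for Ski6, 1431 to 2304 for Dis3, 511 (GFP 1) to 1578 (Rrp6 1) for Rrp6, 954 (Rrp47 1) to 2285 for Rrp47, 1613 (Rrp6 2) to 4466 for core against Rrp6 and Rrp47, 768 (Dis3 2) to 3186 for core against Dis3, 1010 to 1429 for Dis3 against Rrp6, 969 (Rrp47 1) to 2270 for Rrp6 against Rrp47, 4265 to 5891 among depletions, 4987 to 6493 for one against the other 8, and 100 to 201 shared. The list tests were rerun only without GFP 1 (88 calls) and without GFP 2 (87 calls), not without any of the other 20 arrays. Other single arrays that moved a count by over 1.5 times were GFP 1 for Rrp40 (1068), Mtr3 (1098), Rrp46 (1007) and Ski6 (1249), Rrp40 2 (1116), Rrp46 1 (973), Ski6 2 (1273), Rrp47 2 for Rrp47 (1033) and for Rrp6 against Rrp47 (1018), and Rrp47 1 for core against Rrp6 and Rrp47 (2095). Target levels ranged from 2.32 to 3.03 (Csl4), -1.30 to -0.07 (Rrp4), 1.73 to 1.94 (Rrp40), -0.77 (Mtr3 2) to 1.72 (Mtr3 1) for Mtr3, 0.14 to 0.86 (Rrp46), 2.02 to 2.79 (Ski6), -1.53 to -0.81 (Dis3), -1.37 to -0.45 (Rrp6) and 1.19 to 2.21 (Rrp47).

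Apart from the targets given above, the named genes that reversed were list members. With the values as deposited, in Rrp4 against GFP, Rrp40 was at 0.65, Mpp6 at 0.81, mRpL41 at 0.77, mRpL52 at 0.39, ND-B18 at 0.67 and RpLP0-like at 1.00, in Mtr3 Rrp40 at 0.077 and in Ski6 CycB at 0.093. In core against Dis3, also as deposited, Csl4 was at 0.14, Mpp6 at 0.30, Mtr4 at 0.22, Rpn12 at 0.26, Rrp40 at 0.067, Rrp45 at 0.29 and Rrp46 at 0.056, and in core against Rrp6 and Rrp47, CG3909 was at 0.12, Mtr4 at 0.18 and Rrp45 at 0.19. With median centring, RpS28b in Rrp4 was at -0.35. Deposited values carry the median shifts of whole arrays, which quantile normalization removes.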

Other observations

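Members of the exosome list other than the depleted gene itself were called in all depletions but Rrp6. The helicase gene Mtr4 was higher in the arrays labelled Dis3 (0.69 ± 0.16, log2 fold change against GFP ± SE, adjusted p = 0.0061). Csl4 (1.00 ± 0.26), Rrp46 (0.97 ± 0.24) and Rrp45 (0.61 ± 0.20) were also higher there and tst, the helicase of the cytoplasmic exosome, was lower (-1.32 ± 0.39), but these 4 calls were lost without Dis3 2 (adjusted p = 0.13, 0.072, 0.3 and 0.24), as were those of Rrp46 (0.081), Rrp45 (0.26) and tst (0.26) without GFP 1 and that of Csl4 (0.071) without GFP 2. Rrp45 was also higher in Csl4 (0.61 ± 0.20), a call lost without GFP 1 (adjusted p = 0.26), Csl4 1 (0.13) or Csl4 2 (0.1).

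Rrp40 was lower in the arrays labelled Rrp4 (-1.01 ± 0.20, adjusted p = 0.0021) and Mtr3 (-0.97 ± 0.24, adjusted p = 0.0069), though with the values as deposited it was at 0.65 and 0.077, and its call in Mtr3 was lost without Mtr3 2 (adjusted p = 0.061). Mpp6 was lower in Rrp4 (-0.91 ± 0.23), where it was at 0.81 with the values as deposited, and in Rrp40 (-1.01 ± 0.26). Without GFP 1 neither call of Mpp6 held (adjusted p = 0.08 and 0.073), nor the latter without Rrp40 1 (0.099). CG8777 was lower in Rrp46 (-0.91 ± 0.23), a call lost without GFP 1 (adjusted p = 0.081) or Rrp46 1 (0.14), and in Rrp40 (-0.72 ± 0.23), a call lost without any 1 of GFP 1 (0.19), GFP 2 (0.067), Rrp40 1 (0.17) and Rrp40 2 (0.11).

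Trf4-1, the noncanonical poly(A) polymerase, was higher in 5 of the 9 depletions, from 1.69 ± 0.55 in Ski6 to 2.17 ± 0.55 in Rrp46, and these 5 calls were lost without GFP 2 (adjusted p from 0.074 in Rrp46 to 0.19 in Rrp47).

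Among the lists with no list test, the neuronal marker brp was lower in the arrays labelled Csl4 (-2.91 ± 0.62, adjusted p = 0.0029) and Rrp47 (-2.70 ± 0.62, adjusted p = 0.0052). The call was lost in Csl4 without Csl4 2 (-1.66, adjusted p = 0.066), and in Rrp47 without GFP 2 (-2.12, adjusted p = 0.07) or Rrp47 1 (-2.48, adjusted p = 0.054). The other measured neuronal marker, elav, moved the opposite way in Csl4 (0.97 ± 0.23, adjusted p = 0.0065) and was higher in Rrp46 (0.74 ± 0.23, adjusted p = 0.032) and in the core class than in Rrp6 and Rrp47 (0.36 ± 0.13, adjusted p = 0.04). Without GFP 1, elav was not called in Csl4 (0.71, adjusted p = 0.091) or Rrp46 (0.475, adjusted p = 0.3), nor in Rrp46 without Rrp46 1 (adjusted p = 0.077) or Rrp46 2 (adjusted p = 0.2). In the core class its call was lost without any 1 of Csl4 1, Mtr3 2, Rrp4 1, Rrp4 2, Rrp6 2, Rrp40 1, Rrp40 2, Rrp46 2, Rrp47 1, Rrp47 2 and Ski6 2 (adjusted p = 0.051 to 0.19). Between Rrp6 and Rrp47, brp was higher in Rrp6 (2.76 ± 0.62, adjusted p = 0.0043), and not called without Rrp6 1 (2.21, adjusted p = 0.052). The muscle marker Prm was higher in the core class than in Rrp6 and Rrp47 (2.06 ± 0.53, adjusted p = 0.0068), and not called without Rrp6 2 (1.35, adjusted p = 0.087).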
